A study of Mus musculus with 16 samples.

How the data were processed

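The series holds single-end eCLIP libraries of PGC-1α from mouse primary hepatocytes, per the labels. Cells were crosslinked with ultraviolet light at 254 nm and 400 mJ/cm2, and treated cells had received 200 nM glucagon for 3 h after a night in starvation medium, per the labels' protocols. Of 16 libraries, 8 are IP libraries (control or glucagon, lower or upper band, replicates 1 and 2) and 8 are inputs. The 8 IP libraries each had a peak file. Input read values were not analysed here. Groups were taken from the source names of the samples.

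Reads were trimmed with cutadapt and aligned with STAR to mm10, per the submitters' processing notes, which give no versions. The peak caller and the rule behind the reproducible lists are not given in the sources used here. Each file lists regions with position and strand and 2 values. The first deposited value behaves as a −log10 p-value of enrichment over input, capped at 400, and the second deposited value as a log2 fold over input, both read from the values in the files since the files have no header. The deposited files cover each library separately, and 1 further list per group holds reproducible peaks. Every coordinate of the reproducible lists matched a cluster of one of the group's 2 libraries, and their lowest log2 fold was 3.00. The fold and p-value of each peak are the authors' and served to describe, rank or filter peaks within a list. The fold also entered 1 test, of intronic clusters near the 5′ ends of genes. Coordinates are given 1-based on mm10.

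From these files clusters with a −log10 p of at least 3 and a log2 fold of at least 3 were taken as enriched peaks. Each peak was placed by its midpoint and strand in the GENCODE M21 annotation of the same build, in the order coding sequence, 3′ UTR, 5′ UTR, noncoding exon, intron within 500 nt of an exon, deeper intron, and outside genes. Readthrough transcripts were left out, and a peak inside several genes was given to the one with the highest class, then to a protein-coding gene. Overlaps required 1 shared base on the same strand. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1. Overlap counts were checked against bedtools on 4929 peaks, with a difference of 0.

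Depth could only be judged from the number of clusters, since the files give no read counts, and intervals on read counts could not be formed. Glucagon lower band replicate 1 had 26279 clusters and the others 97629 to 260814. Exact 95% binomial intervals (Clopper-Pearson) of the intronic share cover counting error only and ranged from 73.3% to 78.7% in that library and from 86.2% to 87.7% in glucagon upper band replicate 2.

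Treatments were compared by exact two-sided permutation of labels within bands, and bands within treatments, over 36 assignments. Enriched peaks were compared with all clusters of the same libraries by exact sign flips over 8 libraries (256 assignments, smallest possible p 0.00781). Lower and upper band libraries counted as separate units in it, and whether they were independent is not known. Replicate overlap was set against 100 random draws of clusters matched on length. Peaks found in one treatment were counted beside the other ways of splitting 4 libraries into pairs; single peaks were not tested. For 18 gene lists the number of members with a reproducible peak was set against 10000 random lists matched on decile of cluster number among 12845 genes with a cluster, a permutation of list membership, with Benjamini-Hochberg adjustment over the 17 lists with such members. On simulated data for this step, 1% of lists of 40 genes with no effect and 99% of lists bound 4 times as often had p under 0.05. Binding was simulated from cluster number alone, the matched variable, and weaker effects were not simulated. Genes are not independent replicates in this test.

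The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took per reproducible list the 6 genes with the highest fold; per band and direction the 6 genes with the highest fold whose peak was listed in one treatment and overlapped no enriched peak of the other; the 6 genes with most reproducible peaks; up to 10 genes in all 4 lists by fold; and up to 5 members of each gene list. Other genes were named after their values were seen. These are Atf3, Lpin1, Per1, Slc25a25, Alb, Apob, Fn1, C3, C4b, Gc, Rbp4, Rbms1, Tbc1d8, Gm13594, Lncpint, Gfra1 and Plin4. Alternatives covered the fold and p thresholds, the overlap rule, the order of gene regions, each library left out, a replicate block, and the matching of gene lists. The planned comparison of peak sequences was not run, because a genome sequence was not used here. Some genes that the rule takes are not reported here.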

Results

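PGC-1α, a transcriptional coactivator that drives the fasting programme of the liver and carries RNA-binding motifs of its own, was immunoprecipitated with its crosslinked RNA from primary hepatocytes of C57BL/6J mice. Cells were left untreated or given 200 nM glucagon, the pancreatic hormone of fasting, for 3 h. RNA attached to the protein was sequenced by a single-end form of eCLIP, in which ultraviolet light links RNA to protein and sites are read out against a size-matched input. Each library came from a lower or an upper band. With 2 replicates of each treatment and band there were 8 immunoprecipitated (IP) libraries in 4 groups, and the series also lists 8 inputs. The labels do not say whether replicates were separate cultures or animals, so the p-values below measure only the spread between these libraries, which may be technical. The IP libraries held 26279 to 260814 clusters, regions of piled-up reads that each have a fold over input and a p-value. Read depth per library is unknown. The lower band replicate 1 with glucagon had 26279 clusters and the next smallest library 97629.

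The first question was which RNAs PGC-1α crosslinked to in hepatocytes. The authors' reproducible lists, 1 per group, held 2206 peaks in the control lower band, 3692 in the control upper band, 413 in the glucagon lower band and 2167 in the glucagon upper band. Of these peaks 1420, 2129, 329 and 1437, in the same order, overlapped an enriched peak in both libraries of their group. The rest overlapped none in at least 1 of the 2 libraries. All listed peaks fell in 1215 genes, and 86 genes had a peak in all 4 lists. The long noncoding RNA Neat1, the scaffold of nuclear paraspeckles, had by far the most, with 182 peaks in the control lower band, 222 in the control upper band, 175 in the glucagon lower band and 233 in the glucagon upper band, on chromosome 19 at 5824708 to 5845478 of mm10. It supplied 42.4% of the glucagon lower band list and 6.01% to 10.8% of the other lists. Agap1, which encodes an Arf GTPase-activating protein, had 170 peaks over the 4 lists, the gene 2900026A02Rik had 102, Myh9, the heavy chain of a nonmuscle myosin, had 88, and the transcriptional coregulator gene Zmiz1 had 85.

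The peaks with the highest fold over input in each list, given here as the authors deposited it for each peak, were mostly intronic. In the control lower band list the peak of Chd7, a chromatin remodeller, lay in an intron on chromosome 4 at 8691638 to 8691700, 1263 nt from the 5′ end of the gene, with a log2 fold of 5.64. Ncoa2, a p160 coactivator of nuclear receptors, had an intronic peak on chromosome 1 at 13373120 to 13373212 (log2 fold 5.60, with 5.60 ± 0.20 in its own libraries, SD, n = 2). Eif4a1, which encodes a translation initiation helicase, had a peak within 500 nt of an exon on chromosome 11 at 69671989 to 69672072 (5.55, with 5.45 ± 0.25, SD, n = 2). In the control upper band the leading peaks included Ctnnb1, which encodes β-catenin (chromosome 9, 120933937 to 120933987, intron, 5.87), Pum2, an RNA-binding repressor (5′ UTR, 5.71), Ddx6, a helicase of mRNA decay (5.49, with 5.05 ± 1.37, SD, n = 2), and Zeb1, a zinc finger repressor (5.43). In the glucagon upper band they included Cdk17 (5.87, with 5.63 ± 2.19 in its own libraries, SD, n = 2), the splicing regulator gene Hnrnpf (5.86) and Dcun1d4 (5.68). Cebpa, the hepatocyte transcription factor C/EBPα, had coding-sequence peaks in all 4 lists. Its highest spanned chromosome 7 at 35120022 to 35120026, with 6.42 ± 0.67 (SD, n = 2) in the glucagon upper band. In Gm47283, an annotated gene on chromosome Y, a control lower band peak at 90788837 to 90788908 had a log2 fold of 5.91, above that of Chd7. This peak was at the cap of −log10 p, 400, as were the leading Neat1 peaks of all 4 lists and 120 to 405 clusters in each library.

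PGC-1α peaks lay mostly in introns. Enriched peaks, taken as clusters with a −log10 p of at least 3 and a log2 fold of at least 3, were intronic in 83.7% ± 3.86 of cases (SD, n = 8 libraries), against 64.6% ± 10.8 of all clusters of the same libraries. The difference of 19.1 ± 7.60 percentage points was positive in 8 of 8 libraries (exact sign-flip test, two-sided, p = 0.00781, adjusted p = 0.0125 over 8 regions). This p is the smallest that 256 sign flips can give, with the lower and upper band libraries counted as separate units. Introns within 500 nt of an exon accounted for most of the difference. They held 27.0% ± 2.40 of enriched peaks and 13.1% ± 2.45 of clusters (exact p = 0.00781, adjusted p = 0.0125, n = 8). Deeper introns held 56.7% and 51.5% and did not pass the test (exact p = 0.0859, adjusted p = 0.0982, n = 8). Noncoding exons, which include Neat1, were also higher among enriched peaks, at 10.3% ± 2.68 against 4.84% ± 0.224 (exact p = 0.00781, n = 8). Without Neat1 the noncoding exon difference was 0.572 points and no longer passed (exact p = 0.0547, n = 8), while the difference of deeper introns was 8.27 points and passed (exact p = 0.0234, n = 8).

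**Figure D1:**
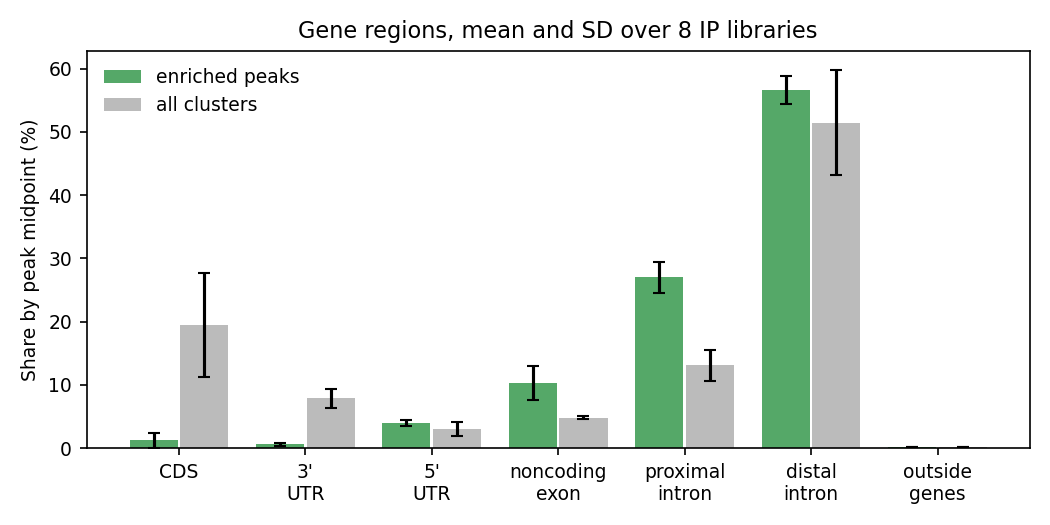
Share of peak midpoints (%) in each gene region for enriched peaks (green) and for all clusters (grey) of the 8 IP libraries. Bars are means and error bars SDs over libraries; coding sequence fell from 19.5% of clusters to 1.28% of enriched peaks, while proximal introns rose from 13.1% to 27.0%.

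Spliced sequence was correspondingly rare. Coding sequence made up 1.28% ± 1.19 of enriched peaks against 19.5% ± 8.23 of clusters, and 3′ UTRs 0.586% ± 0.298 against 7.89% ± 1.48, both lower in all 8 libraries (exact p = 0.00781, adjusted p = 0.0125, n = 8). The 5′ UTRs of genes such as Pum2, Matr3 and Atp5a1 held 3.97% ± 0.514 of enriched peaks and 3.04% ± 1.07 of clusters (exact p = 0.0313, adjusted p = 0.0417, n = 8), and this difference changed sign, to −1.30 points, when introns were given precedence over exons. In the reproducible lists 79.5% of control lower band, 83.7% of control upper band, 45.3% of glucagon lower band and 77.6% of glucagon upper band peaks were intronic. Without Neat1 these shares were 86.6%, 89.0%, 78.6% and 87.0%.

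Genes for secreted proteins had fewer bound members than random lists. Among 51 genes for abundant secreted proteins, such as Alb (albumin), Apob (the apolipoprotein of very low density lipoprotein), Fn1 (fibronectin) and C3 (complement), none had a reproducible peak, where random gene lists matched on the number of clusters held 10.9 on average (permutation of list membership among genes, two-sided, p = 0.0004, adjusted p = 0.0068 over 17 lists). These genes had 11274 clusters over the 8 libraries and 4 enriched peaks, in C4b, Gc and Rbp4. The call was lost when genes were matched on intronic clusters and only intronic peaks were counted, since 22 of the 51 genes then had a cluster and 0.857 bound genes were expected by chance (adjusted permutation p = 1).

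Response genes of glucagon and cyclic AMP were bound in 11 of 37 cases, against 5.38 in matched random lists (permutation p = 0.0160, adjusted p = 0.0907). They included Sik1, a cAMP-induced kinase that restrains CREB coactivators (9 peaks in the glucagon upper band), Klf15, a regulator of amino acid catabolism in fasting, Foxo1, a fasting transcription factor held back by insulin, and Nfil3, a repressor of the clock output. Circadian clock genes were bound in 8 of 22 cases against 3.24 (permutation p = 0.0100, adjusted p = 0.0850), among them Rora, Csnk1d and Csnk1e. Splicing factors were bound in 23 of 76 cases against 15.3 (permutation p = 0.0304, adjusted p = 0.129), including Hnrnpf, Hnrnpk, Matr3, Luc7l3 and Srpk1. None of these 3 lists passed the adjusted threshold in the union of the 4 reproducible lists. With intronic peaks alone the glucagon and cAMP list and the clock list did (adjusted permutation p = 0.0374 each) and splicing factors did not (0.292). With matching on intronic clusters as well, splicing factors did (20 against 10.1, adjusted permutation p = 0.0204), and the other lists did not (0.0680 and 0.0873). With the glucagon lists alone the glucagon and cAMP list (10 against 3.10, adjusted permutation p = 0.0068) and the clock list (7 against 1.84, adjusted p = 0.0136) did, and with both control lists splicing factors did (23 against 13.5, adjusted p = 0.0397), as did urea cycle and amino acid catabolism in the direction of fewer (1 against 6.80, adjusted p = 0.0397). In the single lists splicing factors passed in the glucagon lower band (8 against 1.36, adjusted permutation p = 0.0034) and not in the glucagon upper band (14 against 8.66, adjusted permutation p = 0.302) or either control list (adjusted permutation p = 0.0756 and 0.223). The glucagon and cAMP list passed in the glucagon lower band (4 against 0.448, adjusted permutation p = 0.0187) and upper band (9 against 3.03, adjusted permutation p = 0.0113), and the clock list in the glucagon upper band (7 against 1.80, adjusted permutation p = 0.0113). Differences between lists of the treatments were not tested. Matching used clusters summed over all 8 libraries, for the lists of 1 treatment too. It therefore did not adjust for genes with more RNA in that treatment.

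**Figure D2:**
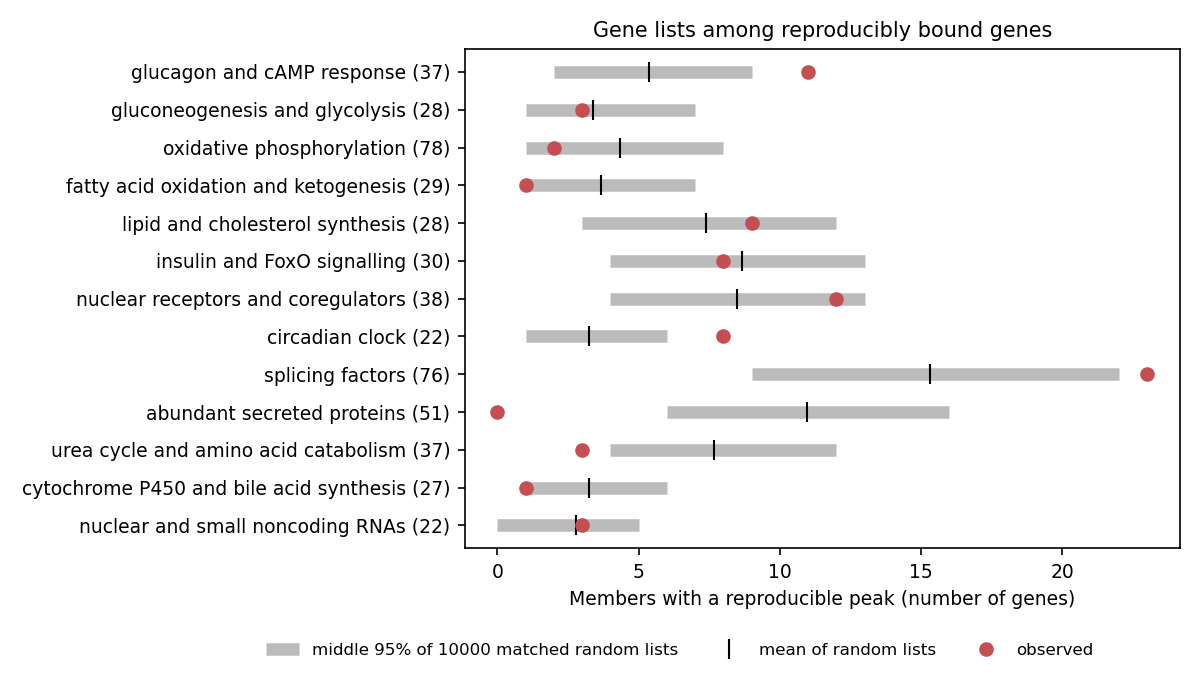
Number of genes of each list with a reproducible peak in any of the 4 groups (red points), with the mean (black ticks) and middle 95% (grey bars) of 10000 random lists matched on cluster number; members with a cluster are in brackets. Secreted proteins sit at 0 against a mean of 10.9, and glucagon and cAMP response genes at 11 against 5.38.

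In the union of the 4 lists none of the lists of metabolic enzymes passed the test. Gluconeogenesis and glycolysis had 3 of 28 members, Gpi1 (glucose-6-phosphate isomerase), Got1 (aspartate aminotransferase) and Ldha (lactate dehydrogenase), against 3.40 by chance (adjusted permutation p = 1). Fatty acid oxidation and ketogenesis had 1 of 29, Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria (3.66 by chance, adjusted permutation p = 0.424). Oxidative phosphorylation had 2 of 78, the ATP synthase subunits Atp5a1 and Atp5c1 (4.36 by chance, adjusted permutation p = 0.639), and the cytochrome P450 and bile acid list had 1 of 27, the reductase Por (3.25 by chance, adjusted permutation p = 0.513). Urea cycle and amino acid catabolism had 3 of 37, Got1, Oat and Slc38a4 (7.67 by chance, adjusted permutation p = 0.158). Lipid and cholesterol synthesis had 9 of 28, with Srebf1, Srebf2, Gpam, Lpin2 and Dgat2 among them (7.39 by chance, adjusted permutation p = 1). Insulin and FoxO signalling had 8 of 30, including Akt1, Foxo3, Pdpk1 and Grb10 (8.65 by chance, adjusted permutation p = 1). Nuclear receptors and their coregulators had 12 of 38, including Rxra, Ncoa2 and Ncoa3 (8.47 by chance, adjusted permutation p = 0.471), and nuclear and small noncoding RNAs had 3 of 22, Neat1, Dleu2 and Airn (2.78 by chance, adjusted permutation p = 1). No marker gene of Kupffer, endothelial or stellate cells or of cholangiocytes had a reproducible peak, and 2, 4, 2 and 4 of them had any cluster. Of the markers of erythroid cells 0 had a cluster. For the former 4 lists 0.0244, 0.0042, 0.0046 and 0.0524 bound genes were expected by chance. Their lack of peaks therefore says nothing about cell types.

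The series title links PGC-1α-bound RNAs to glucagon, which the comparison of treated with untreated cells addresses. Single genes differed in the number of enriched peaks between treatments. Klf15 had 0 in each of the 4 control libraries and 1, 7, 2 and 10 in the glucagon libraries (lower band replicates 1 and 2, then upper band replicates 1 and 2). Cpt1a had 5, 10, 7 and 12 in the control libraries, in the same order, and 17, 23, 13 and 32 with glucagon, and Elmo1, an activator of Rac signalling, had 0 in every control library and 0, 5, 5 and 14 with glucagon. Por had 0, 0, 0 and 1 in the control and 2, 5, 2 and 14 with glucagon. In the other direction Agap1 had 98, 112, 116 and 125 in the control and 6, 14, 58 and 80 with glucagon, and Sh3bp4, an endocytic adaptor, and Grb10, an adaptor that dampens insulin receptor signalling, had 1 to 3 in each control library and 0 in every glucagon library. All clusters of these genes, enriched or not, often moved the same way. Sh3bp4 had 39 to 81 clusters per control library and 0 to 8 with glucagon. Klf15 had 6 to 16 and 7 to 39, and Elmo1 27 to 116 and 21 to 382. Of the 3 Klf15 peaks in the glucagon upper band list, at least 1 overlapped control clusters with log2 folds of 3.23 and 3.20 that missed the p threshold. Single genes were not tested; the exact test over the 8 libraries could not have given a p below 0.0556.

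**Figure D3:**
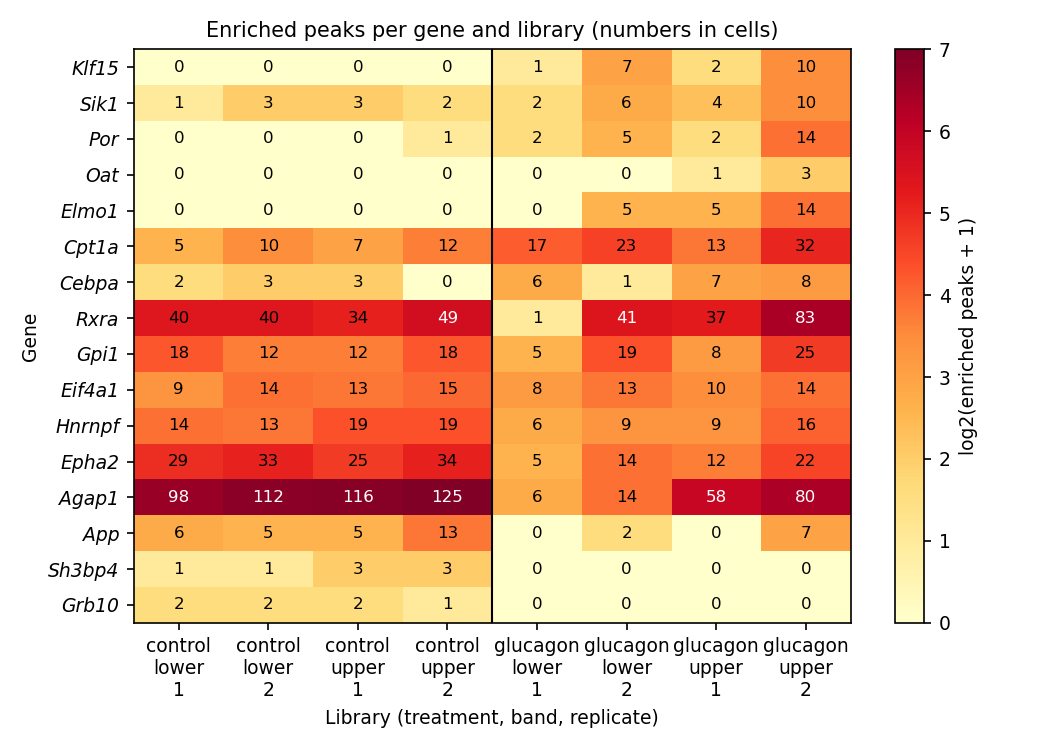
Number of enriched peaks (cell values, colour on a log2 scale of the number plus 1) in 16 of the named genes, by library; the 4 control libraries are left of the line. Klf15 goes from 0 in each control library to 1 to 10 with glucagon, and Agap1 from 98 to 125 down to 6 to 80.

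The number of enriched peaks per library was lower in both glucagon libraries than in both controls of the lower band, and overlapped between treatments in the upper band. It was 4902 ± 1120 in the control and 1898 ± 1299 in the glucagon lower band, and 5726 ± 1127 and 5446 ± 3051 in the upper band (SD, n = 2 each). Averaged over bands the difference, glucagon minus control, was −1642.5 peaks (exact permutation test within bands, two-sided, p = 0.222, n = 4 libraries a side). It was −563.75 without glucagon upper band replicate 1 and −2721 without replicate 2 of that group. As a share of each library's clusters it turned to 0.351 percentage points (exact p = 0.667, n = 4), from −0.535 in the lower band and 1.24 in the upper band, where both glucagon libraries lay above both controls. This test cannot give a p below 0.0556. The intronic share of enriched peaks was 81.6% ± 4.83 with glucagon and 85.7% ± 0.633 in the control, a difference of −4.08 points (exact p = 0.167, n = 4), or −1.72 points without Neat1 (exact p = 0.389). No gene region passed the treatment test (smallest exact p = 0.111, n = 4, for 3′ UTRs).

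**Figure D4:**
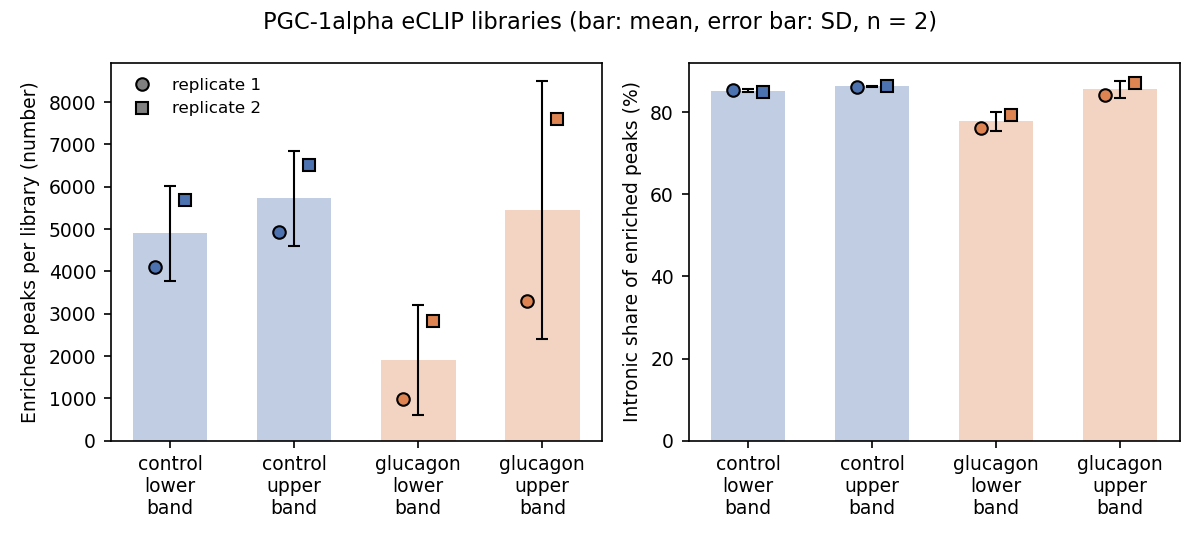
Enriched peaks per library (left, number) and their intronic share (right, %), with circles for replicate 1 and squares for replicate 2; bars are means and error bars SDs of n = 2. The glucagon lower band libraries have 979 and 2816 enriched peaks, below both control lower band libraries at 4110 and 5694.

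Peaks listed in one treatment were often present, below the thresholds, in the other. In the lower band 1315 of the 2206 control peaks overlapped no enriched peak of either glucagon library, and 912 of these overlapped a cluster there. Zmiz1, Epha2 (an ephrin receptor), Rhoq, Agap1, Ehmt1 (a histone methyltransferase) and Rxra (the shared partner of nuclear receptors) had the highest folds among them. The reverse held for 59 of 413 glucagon peaks, led by Akap1 (a mitochondrial kinase anchor), Pacsin2, Raph1, Zmiz1, Lnpep and Neat1. In the upper band 1365 of 3692 control peaks and 628 of 2167 glucagon peaks overlapped no enriched peak in the upper band libraries of the other treatment. Hnrnpf, Agap1, Sh3bp4, Akt1, App (the amyloid precursor protein) and Dleu2 led the control side. In the glucagon upper band libraries Sh3bp4 had 0 enriched peaks in each, App 0 and 7, and each of the others at least 3. Trpc5, Tns1, Elmo1, Cdh10, St6galnac3 and Sc5d led the glucagon side, where the Trpc5 peak, with 5.37 ± 0.27 in its own libraries (SD, n = 2), overlapped control upper band clusters with log2 folds of 3.49 and 2.53. Trpc5, St6galnac3 and Sc5d each had 2 enriched peaks in control lower band replicate 2, and Tns1 had 42 to 56 in each control library. Elmo1 and Cdh10 had 0 in every control library, and Cdh10 also had 0 in both glucagon lower band libraries. Clusters were few in 3 of these genes, with 0 to 2 per library in Cdh10, 2 in Trpc5 and 2 to 4 in St6galnac3. Their leading peaks spanned 19, 21 and 8 nt. Of the glucagon lists 75.1% of lower band and 55.5% of upper band peaks overlapped a control peak of the same band. These shares include Neat1, which supplied 42.4% of the glucagon lower band list and 10.8% of the upper band list.

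Set against other ways of pairing the same libraries, splitting by treatment set apart more peaks in the lower band, which holds the library with the fewest clusters, while in the upper band the order depended on the setting. Peaks enriched in both libraries of one treatment and in neither of the other numbered 707 for the control and 41 for glucagon in the lower band, 748 together, where splitting the 4 libraries by replicate number gave 419 and the crossed split 272. In the upper band they numbered 543 and 302, 845 together, against 871 by replicate number and 659 crossed. The treatment split of the upper band was the higher one at a log2 fold of 2 (2084 against 1781), for genes (207 against 176) and with absence taken as no cluster of log2 fold of at least 1 (205 against 145), and the lower one at a −log10 p of 5 (508 against 580). Of merged enriched peaks, 80.0% in the lower band and 73.2% in the upper band were found in 1 library. Replicates shared 29.8% of enriched peaks in the control lower band, 37.9% in the control upper band, 20.8% in the glucagon lower band and 29.5% in the glucagon upper band, where random clusters of the same lengths shared 1.31% to 2.52%. Enriched peaks of glucagon lower band replicate 2 were found again in replicate 1 in 13.7% of cases and in control lower band replicate 1 in 32.9%.

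Of the 627 genes in the control lower band list 506 were among the 944 of the control upper band list, and of the 110 in the glucagon lower band list 95 were among the 692 of the glucagon upper band list. Ahdc1 had 7 reproducible peaks in the control lower and 24 in the control upper band and Rxra 12 and 22, whereas Myh9 had 32 and 29. Upper band libraries had 5586 ± 1885 enriched peaks and lower band libraries 3400 ± 1997 (SD, n = 4 each), a difference of 2186 (exact permutation test within treatments, two-sided, p = 0.167), and 1107 without glucagon upper band replicate 2. The intronic share was 85.9% ± 1.25 in the upper and 81.5% ± 4.52 in the lower band, a difference of 4.40 points (n = 4 each, exact p = 0.0556, the smallest this test can give, and adjusted p = 0.241 over 13 measures). It was 2.48 points without Neat1 (exact p = 0.111).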

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

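Of 32 measures per library, 3 moved in opposite directions with glucagon in the bands, with both glucagon libraries above both controls in one band and below both in the other, and these differences between bands were not tested. With 2 libraries a side and 32 measures, some such cases can arise by chance. Clusters with a log2 fold of at least 3 that missed the p threshold fell by 2345.5 in the lower band and were 4163.5 more numerous in the upper band. The share of clusters below input was 4.64 percentage points higher with glucagon in the lower band and fell by 4.77 in the upper band. The share of enriched peaks in deeper introns, the class that holds the leading Agap1 and Rxra sites, fell by 5.14 points in the lower band and was 0.952 points higher in the upper band.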

How the results depend on the processing

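The alternatives without Neat1, with 50 bins, with intronic matching, without the glucagon lower band list, with genes of one treatment alone and with absence as no cluster of log2 fold of at least 1 were chosen after seeing the data. None of the permutation tests of treatment or band used here could pass 0.05, so their side of the threshold says nothing about stability. The treatment difference in enriched peaks turned to 0.351 percentage points as a share of clusters, and without 1 library it ran from −2721 to −563.75. Replicate 2 had more clusters and enriched peaks than replicate 1 in all 4 groups. The difference in peak presence between replicates correlated between groups by −0.01 to 0.03 over 19499 merged peaks. Most merged peaks of each band (80.0% and 73.2%) were found in 1 library, which keeps such correlations low. They therefore cannot show whether the number marks a batch, and the labels do not say that it marks a shared culture or day. With the replicate block the differences stayed at −1642.5 and 2186 peaks and −4.08 and 4.40 points, with exact p of 0.250, 0.125, 0.250 and 0.125. Mean replicate overlap of 29.5% became 20.7% at 50% of each peak, 39.7% at a −log10 p of 5 and 42.1% at a log2 fold of 2. At a −log10 p of 5 and log2 fold of 4 the reproducible lists held 386, 559, 58 and 350 peaks (control lower and upper, glucagon lower and upper), and at 50% of each peak 55.4% of lower and 42.8% of upper band glucagon peaks lay in the control list. Treatment-specific peaks, lower then upper band, numbered 1553 and 2084 at a log2 fold of 2, 475 and 508 at a −log10 p of 5, 323 and 207 as genes, and 220 and 205 with the stricter absence. The split by replicate number gave 1781, 580, 176 and 145 in the upper band, so the order of the splits there turned in 3 of these 4 settings. The 5′ UTR excess turned to −1.30 points with introns before exons, and its treatment difference to −0.221 at a log2 fold of 2. Gene lists past the threshold rose from 1 to 7 in an unmatched Fisher's exact test and to 3 each with intronic peaks, control lists and glucagon lists, and was 0 with genes in control lists alone. Bound members above random lists changed sign for gluconeogenesis (0.351 unmatched, 0.0116 with intronic peaks, 1.08 with glucagon lists, 0.591 with intronic matching), insulin and FoxO signalling (5.16 unmatched, 0.796 with glucagon lists) and noncoding RNAs (−0.498 with intronic peaks, −0.663 with 50 bins). With genes in glucagon lists alone it did so for gluconeogenesis (0.585), oxidative phosphorylation (0.341), insulin (0.0951), splicing factors (−1.79), urea cycle (1.17), P450 (0.597) and noncoding RNAs (−0.315), and with genes in control lists alone for glucagon and cAMP (−1.32), lipid synthesis (−0.976), nuclear receptors (−1.42), the clock (−0.378) and noncoding RNAs (−1.10). The causes were not tested. The comparison of sequence content was not run.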

Other observations

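Genes of the glucagon and cAMP list that were bound with glucagon and in no control list were Klf15, Lpin1 (a phosphatidate phosphatase induced in fasting), Pde4d (a cAMP phosphodiesterase), Per1 (a clock gene induced by CREB) and Slc25a25 (a mitochondrial ATP-Mg carrier). These 5 of 37 members compare with 0.651 in random lists matched on clusters of all 8 libraries (permutation of list membership, p = 0.0016, adjusted p = 0.0272 over 17 lists), a comparison chosen after the data were seen, and Atf3 was the 1 member in control lists and no glucagon list (2.32 by chance, adjusted p = 1). Except for Klf15, each had 1 reproducible peak and at least 1 enriched peak in a control library. Clusters with a log2 fold below 1 were used as a rough stand-in for RNA abundance. Relative to all such clusters they were more numerous with glucagon in these 5 genes together (log2 ratio 0.77) and in the other members of the list (1.36). Slc25a25 carried most of the former (71 against 22, 2.37), and Lpin1 (0.36) and Pde4d (0.31) were closer to 0. Klf15 (3 against 9, −0.91) and Per1 (11 against 21, −0.25) had fewer. However, Klf15 clusters of any fold numbered 6 to 16 per control library and 7 to 39 with glucagon. A gene that gains enriched peaks can lose clusters of low fold, so the stand-in is not independent of binding. Among genes outside the naming rule, Gfra1, a co-receptor of glial cell line-derived neurotrophic factor, had 3, 0, 1 and 2 enriched peaks in the control libraries and 10, 29, 12 and 20 with glucagon (lower band replicates 1 and 2, then upper), and the lipid droplet gene Plin4 had 1, 0, 1 and 0 against 1, 7, 6 and 12. The long noncoding RNA Lncpint had 61 reproducible peaks over the 4 lists, and 192 of 2987 genes with an enriched peak had one in all 8 libraries.

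In the 3 patterns and the values that follow, the tests of the glucagon lower band list and the test of log2 fold near 5′ ends were chosen only after the result was seen. The 413 reproducible peaks with glucagon in the lower band against 2206 in the control gave 2 such values. Recovery of replicate 2 peaks in replicate 1, relative to recovery in control lower band replicate 1, was 0.416, and replicate 2 had 0.685 times the enriched peaks of the smaller control library.

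Intronic enriched peaks lay near the 5′ ends of genes, with 38.7% ± 3.20 in the first 5 kb against 14.8% ± 1.66 of other intronic clusters (SD, n = 8, exact sign-flip p = 0.00781). A choice of short genes does not account for it, since within the same genes the shares still differed by 29.0 ± 5.72 points, above 0 in all 8 libraries. Denser reads near 5′ ends could pass the p threshold more easily. The prediction was that the fold would then not differ, whereas within genes the median log2 fold of all intronic clusters was 0.31 ± 0.12 higher there (exact sign-flip p = 0.0156 against a difference of 0.1, n = 8). This does not exclude denser reads, because more IP reads over a scarce input would raise the fold too. Read counts were not available. As first worded, the test of the fold asked for more than 0.1 in all 8 libraries, and 7 met it, the exception being glucagon lower band replicate 1 at 0.04 over 138 genes. No biological explanation was tested, and an IP with another antibody was not analysed here.

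No gene for an abundant secreted protein was bound. One candidate explanation is strong input signal in spliced mRNA of abundant transcripts, which would hide sites outside introns. Matched on intronic clusters with intronic peaks counted, secreted proteins and oxidative phosphorylation both had an adjusted permutation p of 1, the outcome this explanation needs. With 0.857 and 1.92 bound genes expected, however, even 0 could not have passed the threshold, a condition added after the result was seen, and oxidative phosphorylation was not low on cluster number either (adjusted permutation p = 0.639), so input signal and a true lack of binding cannot be told apart.

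In 31 genes, among them Sh3bp4 and Grb10, every control library and no glucagon library had an enriched peak, and in 4 (Klf15, Rbms1, Tbc1d8 and Gm13594) the reverse. Chance is not excluded, since 2 of the 35 splits of the 8 libraries into 4 and 4, the treatment split included, gave as many genes as these 35. The other of the 2 gave 39. It set apart the 4 libraries with the fewest enriched peaks, 3 of them with glucagon, so library size and treatment overlap. That split was uneven in band, with 3 lower band libraries on one side. Among splits with 2 libraries of each band a side, the highest other gave 12 genes. Permutation within bands cannot give a p below 0.0556. More RNA of the 4 genes after glucagon may contribute, as their clusters with log2 fold below 1 were more numerous there (log2 ratio 1.11), mostly in Rbms1. Klf15 had fewer of these, but its clusters of any fold numbered 6 to 16 per control library and 7 to 39 with glucagon. In the 31 genes clusters with log2 fold below 1 were less numerous (−1.03). A change in binding itself stays open and untested.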
